A study of Mus musculus with 13 samples.

How the data were processed

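LK cells came from Boy/J recipients irradiated with 7.0 and 4.75 Gy 3 h apart and transplanted with marrow of one of the 4 genotypes. RNA was amplified with the Ovation RNA-Seq System v2, libraries were made with Nextera XT and sequenced on a HiSeq2500. Per the submitters' processing notes, reads were aligned with TopHat to mm10, counted with featureCounts and handled with limma, whose versions are not given in the sources used here. The values analysed were the deposited per-library values, which are log2 CPM of the voom form, with 0.5 read added to each gene and 1 to each library total. Whole reads were recovered from them for 100% of values within 0.01 read, which settled this form.

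The file held 24062 rows for 13 libraries, and every column of per-sample values was used. Of these rows 4055 had 0 reads in all 13 libraries and 27 carried a date in place of a gene symbol, a spreadsheet conversion, with 2 such names occurring more than once. These rows were kept under the names as they stand. Gene positions, strands, transcript lengths and 3 prime untranslated regions came from GENCODE M21, on GRCm38, which is the mm10 build, and 22724 rows (94.4%) matched by symbol. The transcript length of a gene was that of its longest annotated transcript. Recovered totals were 12.0, 9.82 and 9.75 M reads in WT replicates 1 to 3, 8.38, 11.1 and 12.8 in TIFAB_KO, 8.90, 10.5 and 7.83 in miR-146a_KO, and 9.52, 8.08, 8.68 and 11.7 in dKO replicates 1 to 4. Between 14455 and 16292 rows had a read in a library. Shares of 45S pre-rRNA and of the 10 largest genes (9.75 to 19.8% of reads) served as measures of RNA quality.

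The main test was limma on the log2 CPM as deposited, with 1 mean per group over all 13 libraries (residual degrees of freedom 9) and moderated variances with a trend on mean expression (prior degrees of freedom 9.53). Genes with a mean of at least 0 log2 CPM were tested, 11867 in all, and a Benjamini-Hochberg adjusted p under 0.05 within a contrast was called. The contrasts were each knockout against WT, dKO against each single knockout, and the interaction dKO minus TIFAB_KO minus miR-146a_KO plus WT. The first group named was compared with the second, so a positive log2 fold change is a higher value in the first. Group errors are SD and those of fold changes are SE from limma.

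Gene lists were written from general knowledge of the field and tested with camera of limma at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 27 of 28 lists with at least 5 tested members. The tested and listed members were 44 of 44 TRAF6, Toll-like receptor and NF-kB pathway components, 33 of 42 NF-kB and TLR response genes, 11 of 12 reported miR-146a targets, 30 of 32 del(5q) genes, 48 of 50 interferon response genes and 78 of 79 ribosomal proteins. For cell types they were 32 of 39 erythroid, 25 of 28 megakaryocyte and platelet, 24 of 24 granulocyte-monocyte progenitor, 20 of 31 late granulocyte and 30 of 37 monocyte, macrophage and dendritic cell genes. Further cell types had 22 of 28 mast cell, basophil and eosinophil, 35 of 39 stem cell and multipotent progenitor, 11 of 31 B-lineage, 10 of 28 T and NK cell and 14 of 30 stromal and endothelial genes. For cell states they were 38 of 38 S-phase, 40 of 40 G2 and mitosis, 27 of 30 p53 target, 35 of 40 apoptosis and survival, 36 of 37 immediate early and heat shock and 29 of 32 unfolded protein response genes. The rest were 73 of 74 nuclear respiratory chain, 23 of 24 glycolysis, 27 of 27 cholesterol synthesis, 39 of 48 replication-dependent histone and 5 of 6 Y-linked and X-inactivation genes. Of 15 mitochondrially encoded genes 0 are among the rows, so that list was not tested.

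Genes were named by rule. Tifab and the miR-146a gene came first, in every library, and Traf6, Irak1 and Tifa were given in each contrast against WT. For contrasts against WT and the interaction, up to 10 genes per direction were named by size among those called, with a mean of at least 1 log2 CPM and no overlap between the libraries compared, and up to 5 for dKO against a single knockout. Symbols of unnamed loci, small RNAs and pseudogenes were left out, and the 5 calls this removed are given as outside the rule. Where fewer than 5 passed, those with the smallest unadjusted p filled up to 5 and are given as not passed. Up to 4 members were taken per called list. Some members of these lists are not reported here.

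The tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were no filter, a mean of at least 3 log2 CPM, median centring, quantile normalization, no variance trend, robust variances, library quality weights, limma-voom weights on recovered reads, only the groups compared, a block on replicate number, a fold change of at least 2, an adjusted p under 0.1, an estimated inter-gene correlation and each library left out in turn. The fit without TIFAB_KO replicate 3 and dKO replicate 3 and the removal of a transcript length trend were added after the data were seen.

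A test of the pipeline on simulated values with the spread of each gene in these libraries recovered 61.2 to 65.7% of 2-fold changes in the 5 comparisons of groups, 91.0 to 95.5% of 4-fold changes and 97.0 to 100% of 8-fold changes. The changed genes left out the lowest expressed of those tested, so recovery among these is not known. For the interaction it recovered 22.4, 86.6 and 87.9%. False calls were 4.95 to 7.49% of calls, and the shifted list was called in all 6 comparisons. In dKO against miR-146a_KO 1 list that was not shifted was called too. Genes were drawn independently, so these rates do not cover a structure shared by the libraries. In each simulated comparison 67, 67 and 66 genes were changed at once by these 3 fold sizes. An adjusted p is easier to pass where many genes change, so recovery is lower where few genes differ. In TIFAB_KO against WT, Prom1 (4.90-fold, limma adjusted p = 0.192) and Mras (5.02-fold, 0.429) were not called. The overlap of contrasts that share a group was compared with 100 simulations of unchanged groups. The search for miR-146a seed sites used matches to bases 2 to 8 in 3 prime untranslated regions, with 5 shuffled sites as controls. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.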

Results

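RNA sequencing of lineage-negative, Sca-1-negative, c-kit-positive (LK) bone marrow cells, a fraction rich in committed myeloid, erythroid and megakaryocyte progenitors, was analysed in mouse bone marrow chimeras. The recipients had received marrow that was wild type (WT), lacked Tifab (TIFAB_KO), lacked miR-146a (miR-146a_KO) or lacked both (dKO). Both genes belong to the region lost in human del(5q) disease, and the design asks how the loss of one changes the effect of losing the other. The files hold 3 WT, 3 TIFAB_KO, 3 miR-146a_KO and 4 dKO libraries. The protocol states 3 mice per group, and the labels do not say that each library is a separate mouse. The limma p-values of single genes below therefore measure the spread between libraries. Those of gene lists, from camera at a preset inter-gene correlation of 0.01, rest mainly on the spread between genes. They are not a measure of how well the libraries of a group repeat one another. Positions are those of mm10, and values are log2 CPM, read counts scaled to the total of each library.

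Tifab, which encodes an inhibitor of TRAF6 signalling, was low in every library that lacks it. At chr13:56173704-56178885 it had 40.4, 49.4 and 39.6 CPM in WT replicates 1 to 3 (484, 485 and 386 reads) and 69.2, 70.8 and 64.4 CPM in miR-146a_KO replicates 1 to 3 (616, 746 and 504 reads). TIFAB_KO replicates 1 to 3 had 8.95, 11.7 and 12.8 CPM (75, 130 and 164 reads), and dKO replicates 1 to 4 had 6.20, 4.21, 3.23 and 11 CPM (59, 34, 28 and 129 reads). Reads therefore remained in the knockout libraries, and the part of the gene that the allele removes is not given in the sources used here. The cells came from transplanted recipients, and whether these reads are of donor or recipient cells was not tested. The log2 group means were 5.42 ± 0.18 (SD) in WT, 3.47 ± 0.27 in TIFAB_KO, 6.09 ± 0.07 in miR-146a_KO and 2.48 ± 0.76 in dKO.

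The miR-146a gene (chr11:43374397-43374461) had 0 reads in all 13 libraries, WT included. With 0 reads seen, up to 3 reads would be missed by counting error alone, which is 0.235 to 0.383 CPM in these libraries. Whether the library method captures so short an RNA was not tested, so this is no upper bound on miR-146a. The loss of miR-146a could therefore not be checked from its own row. Lyrm7, the gene most changed in miR-146a_KO and so no independent check of the labels, lay at 1.86, 1.32 and 1.60 log2 CPM in WT, 1.14, 2.52 and 2.33 in TIFAB_KO, 4.72, 4.92 and 4.41 in miR-146a_KO, and 4.82, 4.87, 4.94 and 4.30 in dKO.

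**Figure D1:**
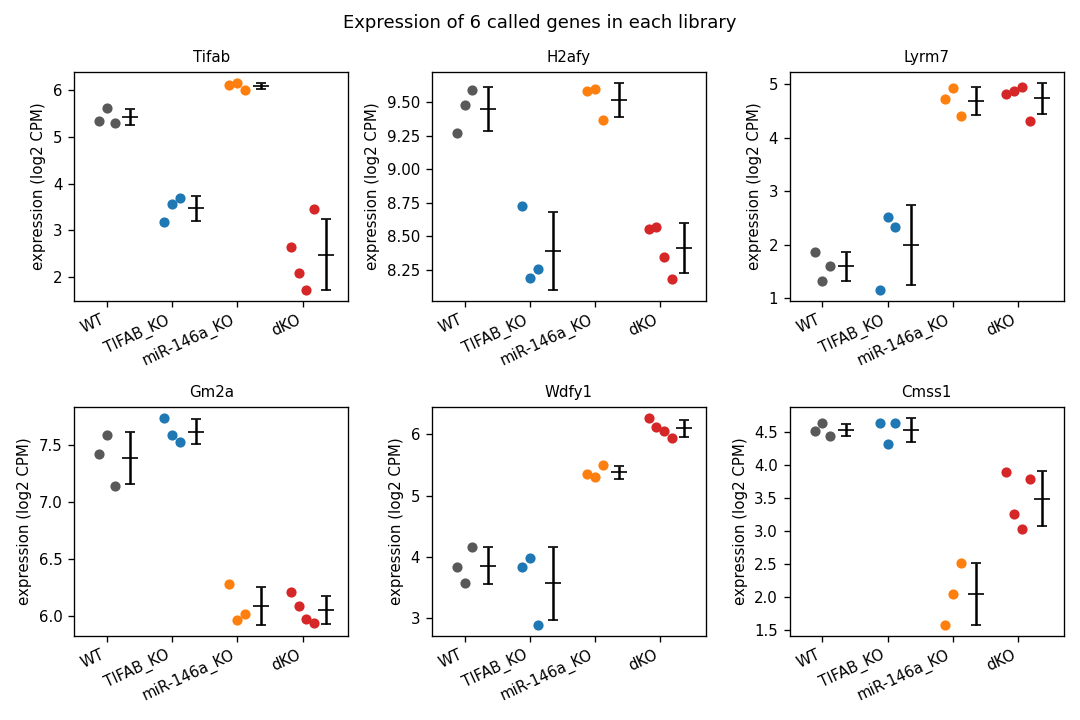
Expression (log2 CPM) of 6 genes in each library, with the mean and SD of each group beside the points.

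Few single genes differed between TIFAB_KO and WT. In TIFAB_KO against WT, 0 genes rose and 2 fell among 11867 tested, and both lie at the Tifab locus. Tifab fell by 1.95 ± 0.31 (log2 fold change ± SE, limma adjusted p = 0.038, n = 3 and 3). H2afy, which encodes a macroH2A histone variant and lies beside Tifab at chr13:56073619-56136361, fell by 1.06 ± 0.16 (adjusted p = 0.038), from 9.45 ± 0.16 (SD) to 8.39 ± 0.29. Of the genes with the smallest unadjusted p that did not pass, the peptide transporter Slc15a2 had 1.89 ± 0.34 (adjusted p = 0.107), the stem cell marker Prom1 2.29 ± 0.46 (0.192) and Nucb2 1.25 ± 0.25 (0.192). Dio2 (1.11 ± 0.23, adjusted p = 0.246), Mras (2.33 ± 0.52), Col5a1 (-1.08 ± 0.26), Txnip (-0.90 ± 0.22) and Atp1b2 (-0.76 ± 0.18, each 0.429) did not pass either. The signalling genes Traf6 (-0.16 ± 0.20), Irak1 (0.08 ± 0.13) and Tifa (0.24 ± 0.22) did not pass (limma adjusted p = 0.999 each).

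The calls of Tifab and H2afy in TIFAB_KO stood near the threshold. Tifab kept its size without each library in turn (-2.06 to -1.80) but missed the threshold without WT replicate 1, 2 or 3, TIFAB_KO replicate 2 or 3, any miR-146a_KO library or dKO replicate 1 (limma adjusted p up to 0.519). H2afy missed it without WT replicate 2 or 3, TIFAB_KO replicate 2 or 3, any miR-146a_KO library or dKO replicate 1 (adjusted p up to 0.508). The number of genes was 4 without WT replicate 1, 44 without TIFAB_KO replicate 1, and 0 without WT replicate 2 or 3, TIFAB_KO replicate 2 or 3, any miR-146a_KO library or dKO replicate 1. An unadjusted p under 0.05 was held by 606 of 11867 genes, about the share of 0.05 that no change would give. Genes are not independent of one another, so with no change this share can still lie above or below 0.05. The same limit holds for the contrasts below.

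Granulocyte-monocyte progenitor genes were higher in TIFAB_KO. All 24 tested members had values above 0 and the list rose (median log2 fold change 0.74, limma camera adjusted p = 4.13e-24, adjusted p = 0.079 with an estimated correlation). Adjusted over the list alone 15 members rose and 0 fell, while over all genes 0 passed and 16 had an unadjusted p under 0.05. Gfi1, a transcription factor of granulocyte development, had 1.31 ± 0.32 (adjusted p = 0.00549 over the list alone), Ms4a3 1.21 ± 0.30 (0.00549), the primary granule protease Prtn3 1.11 ± 0.27 (0.00549) and Dmkn 2.01 ± 0.64 (0.0173). The mean deviation of the list was 0.46 ± 0.18 (SD) in TIFAB_KO and -0.30 ± 0.34 in WT. The call held without each library in turn, with medians from 0.51 to 0.86, and it was 0.71 without TIFAB_KO replicate 3, the library least like the others (median r 0.947, 45S pre-rRNA 10.7% of reads).

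Further lists of mature myeloid cells had positive medians in TIFAB_KO. The mast cell, basophil and eosinophil list rose (0.76, limma camera adjusted p = 1.57e-05, adjusted p = 0.381 with an estimated correlation), with 18 of 22 members above 0, Prg2 at 1.79 ± 0.54 and Ear2 at 1.59 ± 0.68, and its median was 0.36 without WT replicate 3. Late granulocyte genes rose (0.59, adjusted p = 2.63e-04, adjusted p = 0.357 with an estimated correlation), with Lcn2 at 1.32 ± 0.67 and S100a8 at 1.30 ± 0.93. Their median was 0.26 without WT replicate 2 and 0.22 without TIFAB_KO replicate 2, and the call was lost without TIFAB_KO replicate 3 (0.38, adjusted p = 0.0588). Monocyte, macrophage and dendritic cell genes rose (0.19, adjusted p = 1.84e-04, adjusted p = 0.079 with an estimated correlation), with 23 of 30 above 0 and Vcam1 at 1.87 ± 0.54. That median was 0.31 without WT replicate 1 and 0.33 without WT replicate 2, and the call was lost without WT replicate 3 (0.12) or TIFAB_KO replicate 3 (0.16, adjusted p = 0.202). No member of these 3 lists passed over the list alone, and 6, 3 and 7 members had a higher value at an unadjusted p under 0.05.

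Immediate early, heat shock and erythroid genes were lower in TIFAB_KO. Of 36 immediate early and heat shock genes 32 had values below 0 and the list fell (median -0.51, limma camera adjusted p = 1.03e-15, adjusted p = 0.079 with an estimated correlation). Over the list alone 13 fell, among them the stress-induced transcription factor genes Fosb (-1.29 ± 0.36), Atf3 (-1.41 ± 0.49) and Egr3 (-1.61 ± 0.56, adjusted p = 0.044 each), while over all genes 0 passed and 17 had an unadjusted p under 0.05. Of 32 erythroid genes 29 had values below 0 and the list fell (-0.33, adjusted p = 4.45e-10, adjusted p = 0.149 with an estimated correlation). Of these 6 fell over the list alone, with Car1 at -0.74 ± 0.21 and Slc38a5 at -0.77 ± 0.24, and over all genes 0 passed. Both calls held without each library in turn. The megakaryocyte and platelet list did not pass (-0.02, adjusted p = 0.989).

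NF-kB and p53 target genes also had negative medians in TIFAB_KO. The NF-kB and TLR response list fell (-0.31, limma camera adjusted p = 1.6e-06, adjusted p = 0.357 with an estimated correlation), with 26 of 33 below 0, Cd83 at -2.36 ± 0.78 and the feedback inhibitor Tnfaip3 at -1.44 ± 0.41, and its median was -0.57 without TIFAB_KO replicate 1. The p53 target list fell (-0.25, adjusted p = 3.06e-05, adjusted p = 0.079 with an estimated correlation), with 23 of 27 below 0, Perp at -1.20 ± 0.42 and the proapoptotic Pmaip1 at -0.88 ± 0.36. No member of either passed over the list alone, and 7 and 5 members were lower at an unadjusted p under 0.05. The TRAF6 and Toll-like receptor pathway components did not pass (-0.06, adjusted p = 0.825), nor did the miR-146a targets (0.08, adjusted p = 0.989) or the stem cell and multipotent progenitor list (-0.08, adjusted p = 0.257).

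The remaining 4 lists called in TIFAB_KO lost the call without single libraries, and Tifab was the only member that passed. Tifab belongs to the del(5q) list and is the gene lost here, so its fall was set by the design. That list was not tested without Tifab. Histone genes rose (0.24, limma camera adjusted p = 0.00324, adjusted p = 0.485 with an estimated correlation; Hist1h3e 0.66 ± 0.26) but not without WT replicate 3 (0.12) or TIFAB_KO replicate 3 (-0.03, adjusted p = 0.593). Interferon response genes rose (0.16, adjusted p = 0.00381, adjusted p = 0.468 with an estimated correlation; Usp18 0.79 ± 0.40) but not without WT replicate 1 (0.07), TIFAB_KO replicate 2 (0.03, adjusted p = 0.13) or TIFAB_KO replicate 3 (0.18). The del(5q) genes fell (-0.06, adjusted p = 0.0395, adjusted p = 0.32 with an estimated correlation; Tifab, and Egr1 at -0.61 ± 0.23) but not without WT replicate 2 (-0.05), TIFAB_KO replicate 1 (-0.05) or TIFAB_KO replicate 2 (-0.10, adjusted p = 0.212), and their median was -0.09 without WT replicate 1 and -0.01 without WT replicate 3. Cholesterol synthesis genes fell (-0.16, adjusted p = 0.0398, adjusted p = 0.526 with an estimated correlation; Pmvk -0.56 ± 0.28) but not without WT replicate 2 (-0.14, adjusted p = 0.273), TIFAB_KO replicate 1 (-0.19) or TIFAB_KO replicate 3 (-0.10), and the median was -0.26 without TIFAB_KO replicate 2.

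In miR-146a_KO against WT 10 genes differed, of which 6 rose and 4 fell. Lyrm7, which encodes an assembly factor of a mitochondrial respiratory complex and lies on the miR-146a chromosome at chr11:54826866-54860916, rose by 3.09 ± 0.32 (limma adjusted p = 1.23e-04, n = 3 and 3). Gm2a, a lysosomal ganglioside activator gene of the same chromosome (chr11:55098115-55113029), fell by 1.30 ± 0.15 (adjusted p = 3.16e-04). Wdfy1, which encodes an endosomal FYVE-domain protein (chr1:79702262-79776143), rose by 1.53 ± 0.24 (adjusted p = 0.0114), and Cmss1, a gene linked to the small ribosomal subunit (chr16:57302000-57606864), fell by 2.48 ± 0.27 (adjusted p = 1.67e-04). Efcab7 (1.38 ± 0.22, adjusted p = 0.0148), the deiodinase gene Dio2 (1.32 ± 0.23, 0.0257) and the lipid transfer gene Vps13c (1.13 ± 0.20, 0.0257) rose. Outside the naming rule, F630028O10Rik rose (1.26 ± 0.23, adjusted p = 0.0318) and 1700112E06Rik (-2.61 ± 0.34, 9.37e-04) and 2810417H13Rik (-0.77 ± 0.14, 0.0456) fell.

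Tifab did not pass in miR-146a_KO (0.67 ± 0.31, limma adjusted p = 0.522), and neither did Traf6 (0.15 ± 0.20, 0.82) or Irak1 (0.16 ± 0.13, 0.679), both known miR-146a targets, or Tifa (0.10 ± 0.22, 0.89). Ccdc69, a neighbour of Gm2a (chr11:55049731-55078131), had -1.04 ± 0.23 (adjusted p = 0.151), the linker histone gene H1f0 -0.82 ± 0.17 (0.142) and Rab6b -1.31 ± 0.29 (0.151), and these did not pass. The calls of Lyrm7, Gm2a, Cmss1 and 1700112E06Rik held without each library in turn. Those of Wdfy1 and Efcab7 were lost without WT replicate 1 or 2 or miR-146a_KO replicate 2 or 3 (adjusted p up to 0.138 and 0.14), and those of Dio2, Vps13c and F630028O10Rik without any WT or any miR-146a_KO library (up to 0.253, 0.201 and 0.273). That of 2810417H13Rik was lost without any WT or miR-146a_KO library and without dKO replicate 1, 2 or 3 (adjusted p up to 0.365). The number of genes was 4 without WT replicate 1, WT replicate 2, miR-146a_KO replicate 2 or miR-146a_KO replicate 3, and 6 without WT replicate 3. An unadjusted p under 0.05 was held by 1131 of 11867 genes, more than the share of 0.05 that no change would give.

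**Figure D2:**
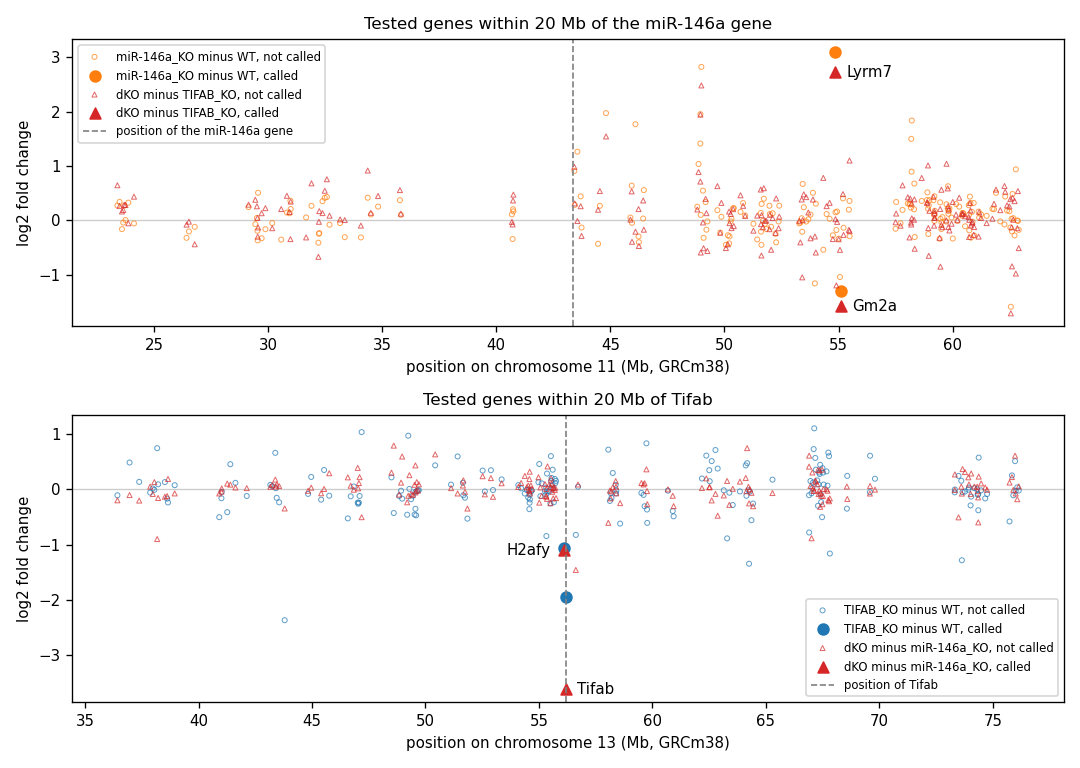
Log2 fold changes of tested genes within 20 Mb of the miR-146a gene and of Tifab, by position, in the contrasts that lose each gene, with called genes filled and named.

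Ribosomal protein and respiratory chain genes were lower in miR-146a_KO. Of 78 ribosomal protein genes 76 had values below 0 and the list fell (median -0.39, limma camera adjusted p = 1.26e-32, adjusted p = 0.641 with an estimated correlation), with Rplp1 at -0.81 ± 0.20, Rps4x at -0.88 ± 0.30 and Rpl14 at -0.90 ± 0.41. Over the list alone 0 passed (Rplp1 adjusted p = 0.0695) and 34 were lower at an unadjusted p under 0.05. Of 73 nuclear respiratory chain genes 60 had values below 0 and the list fell (-0.20, adjusted p = 1e-09, adjusted p = 0.659 with an estimated correlation), with Atp5h at -0.51 ± 0.20 and Cox4i1 at -0.76 ± 0.39. None of them passed over the list alone, 3 were lower at an unadjusted p under 0.05, and the median was -0.11 without miR-146a_KO replicate 3. With total reads as a covariate, the mean difference of respiratory chain genes between the libraries that lack miR-146a and the others was -0.12 ± 0.08, from -0.21 ± 0.09, and no longer lay beyond 2 SE of 0. Reads of ribosomal protein genes can fall on processed pseudogenes, which the 3 tested pseudogene rows did not settle, so their single values are uncertain.

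Platelet genes were lower in miR-146a_KO. The megakaryocyte and platelet list fell (-0.33, limma camera adjusted p = 4.3e-07, adjusted p = 0.641 with an estimated correlation), with 23 of 25 members below 0. The platelet chemokine gene Ppbp fell over the list alone (-1.13 ± 0.25, adjusted p = 0.00732), while Pf4 (-0.73 ± 0.23) and Treml1 (-0.79 ± 0.30) did not pass. Over all genes 0 members passed, 6 were lower at an unadjusted p under 0.05, and the median was -0.14 without miR-146a_KO replicate 1. Erythroid genes fell (-0.17, adjusted p = 0.00166, adjusted p = 0.659 with an estimated correlation; Slc38a5 -0.74 ± 0.24, Car1 -0.62 ± 0.21), with a median of -0.06 without miR-146a_KO replicate 1 and no call without WT replicate 3 (-0.08, adjusted p = 0.223).

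Genes of the unfolded protein response were higher in miR-146a_KO, with 23 of 29 above 0 (0.31, limma camera adjusted p = 0.00948, adjusted p = 0.641 with an estimated correlation). Over the list alone Sdf2l1, a chaperone partner of the endoplasmic reticulum, rose (0.84 ± 0.23, adjusted p = 0.0471), and Calr had 0.66 ± 0.24 and Pdia3 0.53 ± 0.20. The call was lost without miR-146a_KO replicate 1 (0.27, adjusted p = 0.188), and also without a filter on expression. The mast cell, basophil and eosinophil list rose (0.44, adjusted p = 0.00948, adjusted p = 0.659 with an estimated correlation), and over the list alone Cyp11a1 (2.93 ± 0.64, adjusted p = 0.00492) and Gzmb (1.68 ± 0.45, 0.0151) rose. That call was lost without WT replicate 3 (0.28, adjusted p = 0.359) or miR-146a_KO replicate 1 (0.37), and also without a filter on expression. Over all genes 0 members of either list passed. B-lineage genes, 9 of 11 above 0, did not pass (0.65, adjusted p = 0.0758).

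Immediate early and heat shock genes fell in miR-146a_KO (-0.17, limma camera adjusted p = 0.00566, adjusted p = 0.659 with an estimated correlation), and over the list alone 2 fell, among them the immediate early gene Nr4a1 (-1.65 ± 0.42, adjusted p = 0.0315). The list lost its call without WT replicate 2 (-0.17), WT replicate 3 (-0.06) or miR-146a_KO replicate 2 (0.00, adjusted p = 0.464), and its median was -0.34 without WT replicate 1 and -0.27 without miR-146a_KO replicate 1. The miR-146a targets had a median of 0.16 (adjusted p = 0.254), the TRAF6 and Toll-like receptor pathway components 0.16 (0.212), NF-kB and TLR response genes -0.12 (0.0541) and granulocyte-monocyte progenitor genes 0.20 (0.0787), and none of these passed. The median over all tested genes was itself 0.09 in this contrast, 0.08 in dKO against WT and 0.09 in dKO against TIFAB_KO. Positive list medians of that size are therefore no rise over other genes. With each library centred on its median, 4 lists rose and 5 fell in this contrast, against 2 and 5 as deposited. Without single libraries the number of lists reached 12 (WT replicate 1), 11 (miR-146a_KO replicate 2) and 11 (miR-146a_KO replicate 3), against 7.

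In dKO against WT 8 genes differed. Lyrm7 rose by 3.14 ± 0.30 and Wdfy1 by 2.24 ± 0.22, and Tifab fell by 2.94 ± 0.29 (limma adjusted p = 2.72e-05 each, n = 4 and 3). Gm2a fell by 1.33 ± 0.14 (adjusted p = 5.69e-05) and H2afy by 1.04 ± 0.15 (0.00533). The 3 others fell: Tsc22d3, a glucocorticoid-induced gene (chrX:140539528-140600659, -1.63 ± 0.28, 0.022), the LIM-domain gene Crip1 (chr12:113146316-113153879, -1.23 ± 0.19, 0.00782) and the ribosomal stalk gene Rplp1 (chr9:61913284-61914542, -1.16 ± 0.19, 0.015). Slc26a2 (1.07 ± 0.21), Pik3c2a (0.82 ± 0.16) and Adpgk (0.84 ± 0.16) did not pass (adjusted p = 0.0696 each). Traf6 (0.15 ± 0.19, adjusted p = 0.737), Irak1 (0.12 ± 0.12, 0.661) and Tifa (0.02 ± 0.20, 0.968) did not pass.

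Lyrm7, Wdfy1, Tifab and Gm2a kept their calls in dKO against WT without each library in turn. Tsc22d3 lost its call without WT replicate 1 or 2 or dKO replicate 1 or 3 (limma adjusted p up to 0.172), Crip1 without WT replicate 1 or 2 (0.104), Rplp1 without WT replicate 1 or 2 or dKO replicate 1, 2 or 3 (0.178), and H2afy without WT replicate 2 (0.0733). The number of genes was 5 without WT replicate 1, 4 without WT replicate 2, 28 without TIFAB_KO replicate 3 and 336 without dKO replicate 4. An unadjusted p under 0.05 was held by 1668 of 11867 genes, more than the share of 0.05 that no change would give.

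Ribosomal protein genes were lower in dKO than in WT, with 72 of 78 below 0 (median -0.53, limma camera adjusted p = 8.76e-37, adjusted p = 0.555 with an estimated correlation). Over all genes 1 fell (Rplp1), and over the list alone 44 fell and 0 rose, among them Rpl14 (-1.26 ± 0.38, adjusted p = 0.0112) and Rpl30 (-1.86 ± 0.69, 0.0278). Nuclear respiratory chain genes fell (-0.21, adjusted p = 1.73e-10, adjusted p = 0.70 with an estimated correlation), with 60 of 73 below 0, Atp5e at -0.73 ± 0.21 and Cox4i1 at -1.03 ± 0.37. None of these passed over the list alone, and 18 were lower at an unadjusted p under 0.05. Both calls held without each library in turn, but the respiratory chain difference by miR-146a state fell within 2 SE of 0 with total reads as a covariate (-0.12 ± 0.08), while that of ribosomal protein genes did not (-0.35 ± 0.08). Immediate early and heat shock genes fell (-0.25, adjusted p = 2.41e-05, adjusted p = 0.70 with an estimated correlation), 4 over the list alone, including Fosb (-1.30 ± 0.34), Ier5 (-1.20 ± 0.32) and Klf4 (-0.92 ± 0.26, adjusted p = 0.0186 each), and the median was -0.39 without WT replicate 1.

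The other 4 lists called in dKO against WT lost the call without single libraries. Platelet genes fell (-0.27, limma camera adjusted p = 0.00836, adjusted p = 0.73 with an estimated correlation; Pf4 -0.91 ± 0.21, the 1 member lower over the list alone, where 1 was higher) but not without WT replicate 3 (-0.11), dKO replicate 3 (-0.10) or dKO replicate 4 (-0.16, adjusted p = 0.163). NF-kB and TLR response genes fell (-0.19, adjusted p = 0.0142, adjusted p = 0.73 with an estimated correlation; Tnf -0.94 ± 0.39) but not without WT replicate 2 (-0.14, adjusted p = 0.217), dKO replicate 2 (-0.11) or dKO replicate 4 (-0.20), with -0.31 without dKO replicate 3. Genes of G2 and mitosis rose (0.19, adjusted p = 0.0198, adjusted p = 0.73 with an estimated correlation; Ccnb1 0.62 ± 0.19) but not without WT replicate 1 (0.14), WT replicate 2 (0.15), dKO replicate 2 (0.18, adjusted p = 0.11) or dKO replicate 4 (0.20). Mast cell, basophil and eosinophil genes rose (0.48, adjusted p = 0.0198, adjusted p = 0.73 with an estimated correlation; Cyp11a1 2.53 ± 0.60) but not without WT replicate 3 (0.24), dKO replicate 1 (0.38) or dKO replicate 3 (0.26, adjusted p = 0.58). Granulocyte-monocyte progenitor genes (0.16, adjusted p = 0.292), erythroid genes (0.01, 0.30), TRAF6 and Toll-like receptor pathway components (0.12, 0.962) and miR-146a targets (0.15, 0.667) did not pass. After quantile normalization 1 list rose and 5 fell, against 2 and 5 as deposited.

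**Figure D3:**
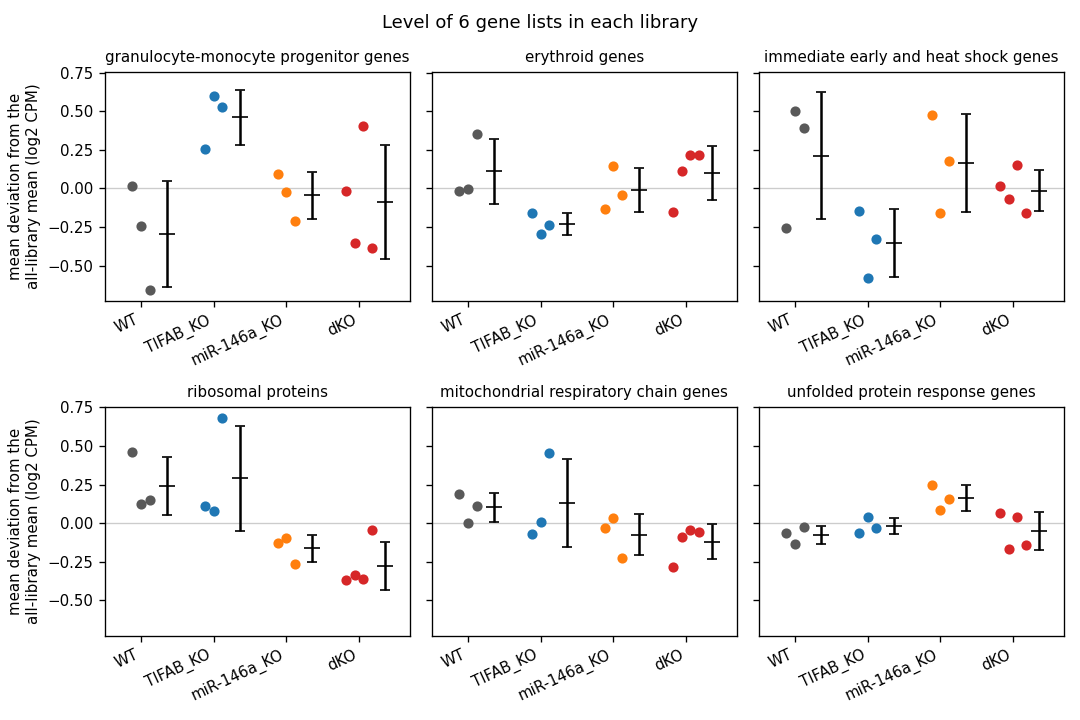
Mean deviation of 6 gene lists from the all-library mean in each library, with the mean and SD of each group beside the points.

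In dKO against TIFAB_KO, which differ by miR-146a, 4 genes differed. Lyrm7 rose by 2.73 ± 0.30 (limma adjusted p = 9.81e-05, n = 4 and 3) and Wdfy1 by 2.53 ± 0.22 (8.85e-06), and Gm2a fell by 1.57 ± 0.14 (8.85e-06). Rplp1 fell by 1.27 ± 0.19 (adjusted p = 0.00785). The erythrocyte ankyrin gene Ank1 (0.79 ± 0.15, adjusted p = 0.0774), Spire1 (0.86 ± 0.17, 0.086), Vps13c (0.89 ± 0.18, 0.13), Rplp2 (-0.87 ± 0.16, 0.0665), Uap1l1 (-1.29 ± 0.24, 0.0665), Crip1 (-0.99 ± 0.19, 0.083) and Tifab (-0.99 ± 0.29, 0.15) did not pass. Lyrm7, Wdfy1 and Gm2a kept their calls without each library in turn, and Rplp1 lost its call without TIFAB_KO replicate 3 or dKO replicate 1 or 2 (adjusted p up to 0.0857). The number of genes was 124 without TIFAB_KO replicate 2 and 278 without dKO replicate 4. Of 11867 genes 2194 had an unadjusted p under 0.05, more than the share of 0.05 that no change would give. After quantile normalization 2 genes rose and 3 fell.

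Ribosomal protein genes were lower in dKO than in TIFAB_KO, with 75 of 78 below 0 (median -0.58, limma camera adjusted p = 5.02e-35, adjusted p = 0.347 with an estimated correlation). Over all genes 1 fell, and over the list alone 53 fell, among them Rps14 (-1.27 ± 0.27, adjusted p = 0.00334), which is itself a gene of the del(5q) interval. The median was -0.33 without TIFAB_KO replicate 3. Nuclear respiratory chain genes fell (-0.26, adjusted p = 6.44e-11, adjusted p = 0.519 with an estimated correlation), with Cox4i1 (-1.29 ± 0.37), Atp5e (-0.78 ± 0.21) and Uqcr11 (-0.78 ± 0.21) among the 4 that fell over the list alone (adjusted p = 0.0457 each) and 0 over all genes. Their median was -0.10 without TIFAB_KO replicate 3, and 22 members were lower at an unadjusted p under 0.05. With the transcript length trend removed the call was lost (-0.06, adjusted p = 0.0522), and with total reads as a covariate the difference by miR-146a state was -0.12 ± 0.08, within 2 SE of 0.

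Granulocyte-monocyte progenitor genes were lower and erythroid genes higher in dKO than in TIFAB_KO. The progenitor list fell (-0.60, limma camera adjusted p = 1.7e-10, adjusted p = 0.347 with an estimated correlation), with 21 of 24 below 0, and over the list alone 12 fell, including Prtn3 (-1.09 ± 0.25, adjusted p = 0.00601), Gfi1 (-1.06 ± 0.30, 0.0131) and the haptoglobin gene Hp (-1.18 ± 0.47, 0.046). Its call held without each library in turn. The erythroid list rose (0.25, adjusted p = 0.00152, adjusted p = 0.675 with an estimated correlation), with 28 of 32 above 0, and over the list alone 9 rose, including Ank1 (0.79 ± 0.15, adjusted p = 0.00146) and Xk (0.72 ± 0.24, 0.0429), but the call was lost without TIFAB_KO replicate 2 (0.22, adjusted p = 0.112). Over all genes 0 members of either list passed, and 13 and 11 had an unadjusted p under 0.05 in these directions.

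Genes of G2 and mitosis rose in dKO against TIFAB_KO (0.23, limma camera adjusted p = 0.00317, adjusted p = 0.752 with an estimated correlation; over the list alone 3 rose, with Ckap2 at 0.68 ± 0.17 and Kif11 at 0.51 ± 0.14) but not without TIFAB_KO replicate 1 (0.20, adjusted p = 0.142). Monocyte, macrophage and dendritic cell genes fell (-0.22, adjusted p = 0.0108, adjusted p = 0.347 with an estimated correlation; Mrc1 -1.29 ± 0.70) but not without TIFAB_KO replicate 3 (-0.04, adjusted p = 0.391). Platelet genes fell (-0.11, adjusted p = 0.0136, adjusted p = 0.752 with an estimated correlation; Itga2b -0.63 ± 0.18) but not without dKO replicate 3 (-0.06) or dKO replicate 4 (-0.08, adjusted p = 0.221), and their median was 0.02 without TIFAB_KO replicate 1, -0.25 without TIFAB_KO replicate 3 and -0.29 without dKO replicate 2. Histone genes fell (-0.22, adjusted p = 0.0359, adjusted p = 0.752 with an estimated correlation; 1 higher over the list alone; Hist1h2bl -0.50 ± 0.21) but not without TIFAB_KO replicate 3 (0.02, adjusted p = 0.916), dKO replicate 1 (-0.19) or dKO replicate 4 (-0.20). Glycolysis genes fell (-0.11, adjusted p = 0.0379, adjusted p = 0.347 with an estimated correlation; Pgam1 -0.66 ± 0.18, the 1 lower over the list alone) but not without TIFAB_KO replicate 1 (-0.09), TIFAB_KO replicate 3 (-0.15, adjusted p = 0.145), dKO replicate 1 (-0.12), dKO replicate 2 (-0.03) or dKO replicate 4 (-0.07), with -0.16 without TIFAB_KO replicate 2. The TRAF6 and Toll-like receptor pathway components did not pass (0.12, adjusted p = 0.888). After quantile normalization 3 lists rose and 6 fell, against 2 and 7 as deposited.

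In dKO against miR-146a_KO, which differ by Tifab, 6 genes differed. Tifab fell by 3.61 ± 0.29 (limma adjusted p = 2.85e-06, n = 4 and 3) and H2afy by 1.11 ± 0.15 (0.00371). Cmss1 rose by 1.45 ± 0.25 (adjusted p = 0.0388) and 1700112E06Rik by 2.09 ± 0.32 (0.00832), the reverse of their falls in miR-146a_KO against WT. Stard6, a lipid transfer gene at chr18:70472454-70501066, rose by 4.21 ± 0.71 (adjusted p = 0.0259), and 4930503L19Rik, which overlaps it on the other strand (chr18:70452212-70472509), by 1.28 ± 0.17 (0.00211). Reads of this overlap may belong to either gene, because the strand of counting is not given in the sources used here. Stard6 had 15, 2 and 0 reads in miR-146a_KO, 47, 46, 52 and 62 in dKO, 26, 20 and 15 in WT and 36, 39 and 63 in TIFAB_KO. Efcab7 (-1.05 ± 0.21, adjusted p = 0.142), H1f0 (0.62 ± 0.16), Nup43 (0.53 ± 0.15), Ppbp (0.81 ± 0.24), Manf (-0.54 ± 0.15) and Tgfbi (-1.46 ± 0.38), a neighbour of Tifab, did not pass.

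Tifab and 4930503L19Rik kept their calls in dKO against miR-146a_KO without each library in turn. Stard6 lost its call in 10 of the 13 (limma adjusted p up to 0.221, 3.10 to 5.49), Cmss1 in all but miR-146a_KO replicate 3 and dKO replicate 3 (up to 0.495), H2afy without miR-146a_KO replicate 2 (0.0585), and 1700112E06Rik without miR-146a_KO replicate 1 or 2 or dKO replicate 2 (0.0664). The number of genes was 2 without miR-146a_KO replicate 2 and 3 without dKO replicate 2. An unadjusted p under 0.05 was held by 229 of 11867 genes, fewer than the share of 0.05 that no change would give.

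Unfolded protein response genes were lower in dKO than in miR-146a_KO, with 26 of 29 below 0 (median -0.19, limma camera adjusted p = 3.54e-07, adjusted p = 0.107 with an estimated correlation). Creld2 had -0.69 ± 0.26, Manf -0.54 ± 0.15 and Sdf2l1 -0.48 ± 0.21, all genes of protein folding in the endoplasmic reticulum. Over the list alone 0 passed, 4 were lower at an unadjusted p under 0.05, and the call held without each library in turn. The mean deviation of the list was -0.08 ± 0.06 (SD) in WT, -0.02 ± 0.05 in TIFAB_KO, 0.16 ± 0.08 in miR-146a_KO and -0.05 ± 0.12 in dKO.

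The other 6 lists called in dKO against miR-146a_KO had 0 members that passed over the list alone, and each lost its call without single libraries. B-lineage genes fell (-0.39, limma camera adjusted p = 0.00416, adjusted p = 0.516 with an estimated correlation; Ebf1 -1.40 ± 0.66) but not without miR-146a_KO replicate 1 (-0.42) or dKO replicate 3 (-0.22, adjusted p = 0.283), with -0.76 without miR-146a_KO replicate 2 and -0.73 without dKO replicate 1. Erythroid genes rose (0.10, adjusted p = 0.00416, adjusted p = 0.972 with an estimated correlation; Slc38a5 0.60 ± 0.23) but not without miR-146a_KO replicate 1 (0.05), dKO replicate 3 (0.03) or dKO replicate 4 (0.09, adjusted p = 0.195), with 0.20 without miR-146a_KO replicate 2 and 0.19 without dKO replicate 1. Ribosomal protein genes fell (-0.09, adjusted p = 0.00416, adjusted p = 0.972 with an estimated correlation; Rplp2 -0.38 ± 0.16) but not without miR-146a_KO replicate 1 (-0.10), miR-146a_KO replicate 2 (-0.05) or dKO replicate 1 (-0.05, adjusted p = 0.45). That median was -0.15 without miR-146a_KO replicate 3, -0.05 without dKO replicate 3 and -0.16 without dKO replicate 4, and the call was lost with the transcript length trend removed (-0.06, adjusted p = 0.0796). Platelet genes rose (0.15, adjusted p = 0.00963, adjusted p = 0.972 with an estimated correlation; Ppbp 0.81 ± 0.24) but not without miR-146a_KO replicate 1 (0.00), dKO replicate 1 (0.11) or dKO replicate 2 (0.03, adjusted p = 0.661), with 0.29 without miR-146a_KO replicate 2 and 0.27 without dKO replicate 4.

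T and NK cell genes fell in dKO against miR-146a_KO (-0.18, limma camera adjusted p = 0.0489, adjusted p = 0.516 with an estimated correlation; Il2rb -0.82 ± 0.35), and the call was lost in 11 of the 13 fits without single libraries (adjusted p up to 0.215). That median was -0.28 without miR-146a_KO replicate 1 or dKO replicate 1, -0.31 without miR-146a_KO replicate 2 and -0.08 without dKO replicate 2. Immediate early and heat shock genes fell (-0.08, adjusted p = 0.0489, adjusted p = 0.972 with an estimated correlation; Hspb1 -2.21 ± 0.74), and the call was lost in 9 of the 13. That median was 0.07 without miR-146a_KO replicate 1 (adjusted p = 0.631), 0.03 without dKO replicate 4, -0.21 without miR-146a_KO replicate 2 and -0.18 without dKO replicate 3. The TRAF6 and Toll-like receptor pathway components did not pass (-0.04, adjusted p = 0.218). The number of lists was 2 without miR-146a_KO replicate 1, 4 without dKO replicate 1 and 11 without dKO replicate 3, against 7. After quantile normalization 2 lists rose and 3 fell, against 2 and 5 as deposited.

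The interaction of both losses, dKO minus TIFAB_KO minus miR-146a_KO plus WT, was called in 0 single genes. The smallest limma adjusted p was 0.541, and limma-voom weights, robust variances, library quality weights and both other scalings also gave 0. Of 11867 genes 502 had an unadjusted p under 0.05, fewer than the share of 0.05 that no change would give. Among the values that did not pass (adjusted p = 0.541 each), Gfi1 had -1.78 ± 0.44, Slc15a2 -1.98 ± 0.47, Dio2 -1.41 ± 0.32, Napsa -1.09 ± 0.25 and Rps6ka1 -0.89 ± 0.21. Atp1b2 had 1.18 ± 0.25, Spire1 1.07 ± 0.24, Rab6b 1.70 ± 0.40, Ptms 1.66 ± 0.40 and Slc38a5 1.37 ± 0.33. Tifab had -1.66 ± 0.43 (adjusted p = 0.599). The number of genes was 1 without TIFAB_KO replicate 1.

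Granulocyte-monocyte progenitor and erythroid genes departed from the sum of the single losses in opposite directions. All 24 progenitor genes had an interaction below 0 (median -0.73, limma camera adjusted p = 7.44e-16, adjusted p = 0.162 with an estimated correlation), and the list, which rose in TIFAB_KO, did not pass in dKO against WT (0.16, adjusted p = 0.292). Over the list alone 5 were lower, including Gfi1 (adjusted p = 0.00961), Prtn3 (-1.49 ± 0.37, 0.00961) and Ms4a3 (-1.33 ± 0.41, 0.0248), and 13 had an unadjusted p under 0.05. Of 32 erythroid genes 26 were above 0 (0.45, adjusted p = 1.62e-10, adjusted p = 0.162 with an estimated correlation), and over the list alone 6 were higher, including Slc38a5 (adjusted p = 0.00928), Car1 (1.12 ± 0.28, 0.00928) and Ank1 (0.90 ± 0.22, 0.00928). Both calls held without each library in turn, and the erythroid median was 0.29 without miR-146a_KO replicate 1. Group means of the progenitor list were -0.30 ± 0.34 (SD) in WT, 0.46 ± 0.18 in TIFAB_KO, -0.05 ± 0.15 in miR-146a_KO and -0.09 ± 0.37 in dKO.

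Immediate early and heat shock genes had a positive interaction (0.40, limma camera adjusted p = 1.71e-05, adjusted p = 0.439 with an estimated correlation), and over the list alone Egr3 (2.68 ± 0.77) and Nr4a1 (2.09 ± 0.57, adjusted p = 0.044 each) were higher. That call was lost without TIFAB_KO replicate 2 (0.24, adjusted p = 0.051), and the median was 0.19 without miR-146a_KO replicate 2. Unfolded protein response genes had a negative interaction (-0.21, adjusted p = 8.09e-05, adjusted p = 0.162 with an estimated correlation), with Sdf2l1 (-1.24 ± 0.31, adjusted p = 0.0242) the 1 member lower over the list alone, and a median of -0.13 without TIFAB_KO replicate 2. Group means of the immediate early list were 0.21 ± 0.41 (SD) in WT, -0.35 ± 0.22 in TIFAB_KO, 0.16 ± 0.32 in miR-146a_KO and -0.01 ± 0.13 in dKO.

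A further 6 lists were called in the interaction, with 0 members passing over the list alone, and each lost its call without single libraries. Mast cell, basophil and eosinophil genes (-0.53, limma camera adjusted p = 0.00137, adjusted p = 0.663 with an estimated correlation; Prg2 -2.11 ± 0.74) lost it without WT replicate 3 (-0.50), TIFAB_KO replicate 3 (-0.57) or dKO replicate 4 (-0.40, adjusted p = 0.105), with -0.80 without WT replicate 1 and -0.86 without miR-146a_KO replicate 3. Monocyte, macrophage and dendritic cell genes (-0.35, adjusted p = 0.00172, adjusted p = 0.162 with an estimated correlation; C1qb -2.11 ± 1.16) lost it without WT replicate 3 (-0.28) or TIFAB_KO replicate 3 (-0.30, adjusted p = 0.189). NF-kB and TLR response genes (0.36, adjusted p = 0.00404, adjusted p = 0.704 with an estimated correlation; Tnfaip3 1.67 ± 0.57) lost it without WT replicate 2 (0.34), TIFAB_KO replicate 2 (0.08, adjusted p = 0.252), miR-146a_KO replicate 2 (0.22) or dKO replicate 3 (0.16), with 0.18 without TIFAB_KO replicate 3. Ribosomal protein genes (-0.14, adjusted p = 0.02, adjusted p = 0.74 with an estimated correlation; Rpl30 -1.23 ± 1.01) lost it in 7 of the 13 fits (adjusted p up to 0.372), and their median ran from -0.23 without WT replicate 1 or TIFAB_KO replicate 2 to 0.06 without TIFAB_KO replicate 3. With the transcript length trend removed this call was lost as well (-0.03, adjusted p = 0.679).

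The p53 target genes had an interaction of 0.19 (limma camera adjusted p = 0.0417, adjusted p = 0.432 with an estimated correlation; Zmat3 0.83 ± 0.36), lost in 6 of the 13 fits (adjusted p up to 0.18), with 0.08 without WT replicate 3, 0.31 without TIFAB_KO replicate 1 and 0.01 without TIFAB_KO replicate 3. Interferon response genes had -0.24 (adjusted p = 0.0477, adjusted p = 0.704 with an estimated correlation; Psmb9 -0.85 ± 0.35), lost in 8 of the 13 (up to 0.252), with -0.36 without TIFAB_KO replicate 1 and -0.08 without TIFAB_KO replicate 2. The number of lists was 6 without WT replicate 3, against 10.

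The contrasts that lose miR-146a were partly alike with and without Tifab. Across 11867 genes, miR-146a_KO minus WT and dKO minus TIFAB_KO, which share no library, correlated at r 0.34 with 67.8% of genes of the same sign (simulated with no change, mean r 0.00, -0.03 to 0.04). The simulation drew genes independently, so its range leaves out any gradient shared by the libraries. The highest r of another division of the same libraries was 0.37. Lyrm7, Wdfy1 and Gm2a were called in both, where independent calls would share 0.00101 higher and 6.74e-04 lower genes. The contrasts that lose Tifab showed no such likeness: TIFAB_KO minus WT and dKO minus miR-146a_KO correlated at r -0.02 with 45.1% of the same sign, and shared Tifab and H2afy. That correlation was -0.07 to 0.04 without single libraries, and that of miR-146a loss 0.22 to 0.41. The correlation of miR-146a loss fell to 0.10 without a filter and was 0.48 among genes with a mean of at least 3 log2 CPM.

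Lyrm7, Wdfy1 and Gm2a were called against WT in miR-146a_KO and dKO (2 higher and 1 lower, independent 0.00101 and 0.00202), and Tifab and H2afy in TIFAB_KO and dKO (2 lower, independent 0.00101). The changes in miR-146a_KO and dKO correlated at r 0.75, where the shared WT libraries alone gave a simulated r of 0.53, and those in TIFAB_KO and dKO at 0.39 against a simulated 0.53. The shared group of 3 libraries cannot be divided into parts of at least 2, so its part was taken off by simulation, which left a covariance of 0.0593 for miR-146a_KO with dKO and 0.00289 for TIFAB_KO with dKO. The simulation drew genes independently and gave r 0.51 to 0.56 for TIFAB_KO with dKO, where the libraries gave 0.39. These remainders are therefore rough values. The overlap with TIFAB_KO was 0 without WT replicate 2 or 3, TIFAB_KO replicate 2 or 3, any miR-146a_KO library or dKO replicate 1, 1 without WT replicate 1 and 4 without TIFAB_KO replicate 1. The overlap with miR-146a_KO was 5 without TIFAB_KO replicate 2, 7 without TIFAB_KO replicate 3 and 9 without dKO replicate 4.

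Some lists were called in no contrast. In dKO against WT their medians were -0.04 for stem cell and multipotent progenitor genes (limma camera adjusted p = 0.146), -0.05 for stromal and endothelial genes (0.894), 0.08 for S-phase genes (0.538), -0.01 for apoptosis and survival regulators (0.894) and 0.06 for Y-linked and X-inactivation genes (0.69). With an estimated correlation 0 lists were called in any contrast. The libraries held 7.83 to 12.8 M reads and 45S pre-rRNA (Rn45s) took 3.85 to 10.7% of them, with group means of 6.98 ± 2.51 (SD), 8.13 ± 2.27, 5.53 ± 1.58 and 5.46 ± 1.11% in WT, TIFAB_KO, miR-146a_KO and dKO. TIFAB_KO replicate 3 and dKO replicate 3 were the least like the others (median r 0.947 and 0.951), and quality weights gave them 0.307 and 0.581.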

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

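The values below were picked out by fixed rules before any cause was looked for, and the tests of both flanks, of mislabelling, of direct seed release, of neighbouring pairs, of pseudogenes, of library size as a whole cause and of progenitor shares were chosen only after the result was seen. In dKO, the only group with 4 libraries, 1 library stood apart from the other 3 for 4 of 76 measures, and about 5% of measures would do so by chance, which is 1 in 20. Mras, a Ras-like GTPase gene, lay at 2.98 log2 CPM in replicate 3 (others 0.88 to 1.20), and Manf, a folding factor of the endoplasmic reticulum, at 5.27 in replicate 1 (others 4.98 to 5.01). The ribosomal protein genes had a mean deviation of -0.043 in replicate 4 (others -0.37 to -0.33), and the S-phase genes -0.072 in replicate 3 (others 0.04 to 0.06). The causes were not tested.

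For 10 lists the effect of one loss differed with the other, by limma camera at the preset correlation. The median interaction was -0.73 for granulocyte-monocyte progenitor, 0.45 for erythroid, 0.40 for immediate early and heat shock, -0.21 for unfolded protein response, -0.53 for mast cell, basophil and eosinophil and -0.35 for monocyte, macrophage and dendritic cell genes. It was 0.36 for NF-kB and TLR response, -0.24 for interferon response, -0.14 for ribosomal protein and 0.19 for p53 target genes. With an estimated correlation 0 of them remained, with a smallest adjusted p of 0.162. Divided in 100 ways, the real one counted, the same libraries gave as many lists in 35, with 10 for the real grouping and up to 16 for another. These divisions mix the genotypes, so they also carry the effects of the single losses. They do not show what an absent interaction would give, and do not decide whether 10 lists are more than chance. For single genes the real grouping gave 0, so all 100 divisions had to reach it and their number says nothing. The highest other gave 1168, which points to a structure of the samples, and as these divisions mix the genotypes they do not show of which kind.

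Divisions of the libraries of 2 groups gave the following, with the real split counted in each number of splits. In TIFAB_KO against WT the 10 splits are too few to judge, with 2 genes (highest other 2, 2 splits as large) and 12 lists (highest other 12, 2 splits). In miR-146a_KO against WT they are too few as well, with 10 genes (highest other 0, 1 split) and 7 lists (highest other 13, 6 splits). In dKO against WT, 8 genes were matched in 3 of 35 splits (highest other 676) and 7 lists in 22 (highest other 15). In dKO against TIFAB_KO, 4 genes were matched in 3 of 35 (highest other 368) and 9 lists in 20 (highest other 15). The splits with 676 and 368 genes set dKO replicate 4 with the other group against dKO replicates 1 to 3, which points to a structure of the samples that was not identified. In dKO against miR-146a_KO the 6 genes were met only by the real split (1 of 35, highest other 1), while 7 lists were matched in 16 (highest other 16).

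Genes called where miR-146a was lost lay near its locus more often than other genes. Gm2a and Lyrm7 were 2 of 9 placed genes within 20 Mb (22.2%), against 215 of 11303 tested (1.90%, one-sided Fisher exact p = 0.0119). This fits DNA of the targeting strain carried beside the allele, but called genes within 5 Mb of one another, counted once, left 1 of 8 (exact p = 0.142, a count added after the first), so flanking DNA stays open. Near Tifab it was H2afy, 1 of 4 (25%) against 203 of 11302 (1.80%, exact p = 0.0699). With called genes within 5 Mb of one another counted once it was 1 of 3 (exact p = 0.0529). Both counts leave flanking DNA or an effect of the allele on its neighbour open. A library mislabelled for Tifab is excluded by the gap of 1.62 between the labelled groups in Tifab, while for miR-146a the gap of 1.78 in Lyrm7 excludes nothing, as Lyrm7 was chosen by these labels. Among genes that rose, Dio2 alone of 5 searched had a seed site (14.0% of all genes searched had one, exact p = 0.53). Dio2 was 6.47 ± 0.29 (SD) in TIFAB_KO and 6.38 ± 0.49 in dKO, so losing miR-146a did not raise it where Tifab was lost too. The exact test does not decide direct release, which stays open. So does an untested effect of miR-146a loss on Wdfy1, Cmss1 and Efcab7, which lie on other chromosomes.

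Ribosomal protein genes were lower in the 7 libraries that lack miR-146a (-0.37 to -0.04) than in the 6 others (0.08 to 0.68), in list calls that were lost with an estimated correlation (limma camera adjusted p = 0.641, 0.555 and 0.347 in miR-146a_KO against WT, dKO against WT and dKO against TIFAB_KO). The length of the longest annotated transcript does not explain it in dKO against WT, where the median was -0.42 with that length trend removed, from -0.53. The lengths of the transcripts present in the cells were not known, so a bias against short ones is not excluded. Total reads go with a part of it: within groups they correlated with the level of these genes (r 0.813, exact p = 0.00791, adjusted 0.0237). With total reads as a covariate the difference was -0.35 ± 0.08, from -0.49 ± 0.12, so they do not account for all of it. For respiratory chain genes -0.12 ± 0.08, from -0.21 ± 0.09, leaves this open. Values were scaled to the total of each library, so total reads may stand for another trait of the libraries, which was not tested. The 45S pre-rRNA share (within-group r 0.488, exact p = 0.162) and reads shared with pseudogenes (median -0.49 over 3 rows) were not decided. A difference in ribosome gene expression due to miR-146a loss stays open, as untested.

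Granulocyte-monocyte progenitor genes were higher in TIFAB_KO, without a call at an estimated correlation (limma camera adjusted p = 0.079). TIFAB_KO replicate 3 does not carry this, as the median without it was 0.71. Handling stress was not decided (within-group r -0.128 with immediate early genes, exact p = 0.394). Nor was a larger share of these progenitors in place of erythroid and megakaryocyte ones, because the erythroid minus megakaryocyte change was -1.46 standard errors where a common fall would leave it near 0. A change within progenitors due to Tifab loss stays open, as untested.

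All genes with a seed site were higher than those without by 0.0579 when miR-146a was lost, inside the range of shuffled sites (0.0539 to 0.0734), and in dKO against TIFAB_KO by 0.0821, below that range there (0.097 to 0.111), so neither contrast showed a general release. The likeness of miR-146a loss in both Tifab states was matched in 2 of 100 divisions (real r 0.34, highest other 0.37), fewer than the 5% set beforehand for excluding a gradient shared by the libraries, but that bound was wrong and the gradient stays open, because one that runs with miR-146a state, as library size does in part, would raise the real division most. It was 0.30 without TIFAB_KO replicate 3, so that library alone does not explain it. Among 13 called genes with a position, Tifab and 1 of the overlapping genes left aside, 1 pair (Gm2a and Lyrm7) lay within 5 Mb, and 0.369 of 10000 random draws had as many.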

How the results depend on the processing

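In TIFAB_KO against WT the 2 genes, Tifab and H2afy, were 0 without a filter, with quantile normalization or without a variance trend, 1 with only the groups compared, and 5 with library quality weights. The 10 genes of miR-146a_KO were 5 without a trend, 89 with only the groups compared and 213 with quality weights, and all 10 were kept with quality weights. The 8 of dKO against WT were 4 without a trend, 13 with only the groups compared, 792 with quality weights and 26 at an adjusted p under 0.1. The 4 of dKO against TIFAB_KO were 7 without a filter and 9 at an adjusted p under 0.1, and the 6 of dKO against miR-146a_KO were 3 without a trend. Quality weights ran from 0.307 in TIFAB_KO replicate 3 to 2.66 in WT replicate 2. With limma-voom weights 2 of 2, 8 of 10, 8 of 8, 4 of 4 and 4 of 6 calls were kept in the same order. The cause of the shifts was not tested.

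With an estimated inter-gene correlation the lists called were 0 in TIFAB_KO, 0 in miR-146a_KO and 0 in dKO against WT, 0 and 0 in dKO against the single knockouts and 0 in the interaction. Without a filter 5 of 7 list calls were kept in miR-146a_KO, 4 of 7 in dKO against miR-146a_KO and 7 of 10 in the interaction. All were kept in the other contrasts. A replicate block gave 281 genes in dKO against WT, 146 in dKO against TIFAB_KO and 3 in dKO against miR-146a_KO, and it takes dKO replicate 4 out of the comparison. The numbers do not pair libraries: residuals of same-number pairs had a median r of -0.02 (2 of 18 over 0.1) and the others 0.01 (8 of 45).

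After the data were seen, 2 more alternatives were chosen. With the transcript length trend removed TIFAB_KO had 1 gene, and the lists were 11 in miR-146a_KO and 12 in dKO against WT and 4 in dKO against miR-146a_KO. It also took away the call of respiratory chain genes in dKO against TIFAB_KO (-0.06, limma camera adjusted p = 0.0522), and there those of monocyte and histone genes. Against WT it ended those of del(5q) and histone genes in TIFAB_KO and of NF-kB and TLR response genes in dKO. Ribosomal protein, T and NK cell and immediate early genes lost theirs in dKO against miR-146a_KO. In the interaction the ribosomal protein and interferon response genes did. Without both libraries least like the rest, dKO against miR-146a_KO had 11 lists, and the interaction of ribosomal protein genes turned from -0.14 to 0.12. The correlation of miR-146a loss in both Tifab states was 0.10 without a filter. The overlap of TIFAB_KO with dKO was 0 without a filter or with quantile normalization, 1 with the length trend removed and 1 without both libraries.

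Without single libraries the genes ran from 0 to 44 in TIFAB_KO, 4 to 12 in miR-146a_KO and 4 to 336 in dKO against WT, 3 to 278 in dKO against TIFAB_KO, 2 to 5 in dKO against miR-146a_KO and 0 to 1 in the interaction. Lists ran from 10 to 14, 6 to 12, 5 to 9, 6 to 11, 2 to 11 and 6 to 14 in the same order. The correlation ran from -0.07 to 0.04 for Tifab loss and 0.22 to 0.41 for miR-146a loss, and the overlap with dKO from 0 to 4 and 2 to 9.

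Depth limits genes near the filter, since 3 reads are 0.235 to 0.383 CPM.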

Other observations

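The values of this part were looked up only after the result was seen, and the covariate of total reads was chosen then too. Cmss1 and 1700112E06Rik fell in miR-146a_KO against WT and were higher again in dKO, in contrasts that share the miR-146a_KO libraries. Cmss1 had 4.52 ± 0.09 (SD) in WT, 4.53 ± 0.19 in TIFAB_KO, 2.04 ± 0.47 in miR-146a_KO and 3.49 ± 0.41 in dKO. 1700112E06Rik had 2.87 ± 0.17, 2.81 ± 0.07, 0.25 ± 0.17 and 2.34 ± 0.52 in the same order. Such genes would follow the donor line if the miR-146a_KO and dKO marrow came from separate crosses, which variants in the reads of these genes would test.

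The higher granulocyte-monocyte progenitor genes in TIFAB_KO (median 0.74, limma camera adjusted p = 0.079 with an estimated correlation, and 0.71 without TIFAB_KO replicate 3) may reflect more such progenitors in the LK fraction or a change within them. Counts of progenitor subsets by flow cytometry in the same mice would decide it. More such progenitors in place of both erythroid and megakaryocyte ones would have both of those lists fall. Their medians were -0.33 (29 of 32 below 0) and -0.02 (14 of 25 below 0). The difference of list means was -1.46 standard errors, which does not decide it. A replacement of erythroid progenitors alone was not tested.

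Lower ribosomal protein genes in libraries that lack miR-146a might partly follow library size or another trait that runs with total reads. The difference was -0.35 with total reads as a covariate, from -0.49. Sequencing the same RNA to equal depth would test size alone. Reverse transcription PCR of Rplp1 and Rps14 on unamplified RNA would test the difference itself. The release of miR-146a targets was not seen over all genes with a seed site (0.0579), and the knockout was not visible in its own row, so small RNA sequencing of the LK cells would show whether WT cells of this fraction express it.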
